A study of Mus musculus with 16 samples.

How the data were processed

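The data were the processed tables deposited for each library, and raw reads were not used here. Small RNA of mature mouse sperm was given by the authors as deposited counts of each distinct sequence, with its length, and all listed sequences were 18 to 44 nt long. The file names call the reads clean, and no alignment, annotation or molecular identifier was recorded. Sperm RNA was taken either whole or after excision of the 30-40 nt part from a gel. Embryos (Smart-Seq2 libraries, 1 pool of 5 embryos each) and islets (stranded mRNA libraries, 3 per group) were given as deposited FPKM per gene, the unit named per the file headers. Per the submitters' processing notes, TopHat2 2.0.8b was used with build mm10 for both, and Cufflinks for the embryos. Normalization beyond FPKM was not stated.

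The groups were taken from the titles of the samples: whole sperm RNA of ND and HFD males, 30-40 nt sperm RNA of ND and HFD males, 8-cell embryos and blastocysts after injection of either RNA at 2 ng per µl, and islets of offspring from such zygotes. The labels mention water injection as a control, but no library of it belongs to the series. The 2 bisulfite libraries of islets were not analysed here. Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, apart from the changes stated below.

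Islet tables held 24486 entries. Genes with at least 1 FPKM in 3 of 6 libraries (11737) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a trend in the prior variance, two-sided, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. The fit had 4 residual degrees of freedom. Gene lists (33 with enough measured genes, of 42 lists fixed for islets or embryos) were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 33 lists. List means per library and shares of FPKM were compared with exact two-sided permutation tests, for which 3 libraries against 3 cannot give a p under 0.1. Start coordinates are the listed start plus 1, since that equals the RefSeq start for 13429 of 22182 symbols matched by name and chromosome, while the listed start itself equals it for 724. All 6 islet libraries had Xist under 1 FPKM and Ddx3y over 1 FPKM.

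Embryo tables were joined by symbol (23976 symbols used once in each table), and 10 genes with a failed status in a library were left out. At each stage the log2 ratio of FPKM + 1 was taken for genes with a mean of at least 10 FPKM over both libraries, and genes with a difference of at least 1 were counted. List medians were set against 10000 random lists matched on size and on expression deciles. An additive limma model of stage and injection over the 4 embryo libraries covered 9603 genes with at least 1 FPKM in 2 libraries, with 1 residual degree of freedom, so the disagreement of the stages serves as its spread. Lists were also compared with random sets of other genes matched on deciles of genomic span, with a bootstrap interval for the list, a test added after the data were seen. Overlaps beside the both-stage counts are the product of both counts over the number of genes.

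Sperm sequences were expressed as RPM of all reads in the table. Shares carry exact Clopper-Pearson intervals and ratios carry exact conditional binomial intervals, both at 95% and for counting error only; a count of 0 allows up to 3 reads. Sequences with at least 100 RPM in either library were counted as different at 2 times or more. For the comparison of both kinds of RNA, log2 ratios used a pseudocount of 1 RPM. Families share the first 15 bases, a grouping not counted among the tests fixed before. The count of reads ending in CCA was added after the data were seen. MicroRNA seed families (27) were set up after the data were seen, from the microRNA lists fixed before, because no hairpin sequences were in the reference used; they count reads of 21-23 nt by bases 2 to 8 and are not matched to precursors or arms. The planned classes of RNA and transfer RNA isoacceptors were not computed for the same reason. Sequences of the gel fraction are printed only with at least 10 RPM in both whole sperm libraries and families only with at least 100 RPM there; these rules were set after the data were seen. They passed over 1 of the 10 most abundant gel-fraction sequences and all of its 5 largest rises and 5 largest falls, and the 5 largest falls of whole sperm. A few sequences and genes that these rules would name are not reported here.

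Named genes in islets were up to 12 per direction among called genes with a mean of at least 5 FPKM and groups that did not overlap, filled to 12 by the lowest unadjusted p. For each list up to 4 members were named by call and then by mean FPKM, and in embryos the 10 largest differences per direction and stage among genes with a mean of at least 10 FPKM. Clone names and genes listed more than once were passed over. Members of embryo lists were chosen for naming after their values were seen, as were genes named beyond 4 per islet list.

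On simulated data, 200 genes were changed in islet-like values of 3 against 3 libraries. Of those changed by 1 on the log2 scale 95% were found, and of those changed by 2 100% were found, with 15 false calls. For the embryo model the shares were 66% and 100%, with 31 false calls. These shares hold for the simulated values only. In the measured islets Nr1d1, with a log2 difference of 1.51, had a limma adjusted p of 0.0748, while Echdc2 at 1.13 passed at 0.0355. In the measured embryos 0 of 9603 genes passed for the injection, Amd2 at -2.59 included (limma adjusted p = 0.387). The sperm counting procedure was tested on simulated data as well: it found 100% of changed sequences, and its intervals covered the true ratio in 95.4% of cases.

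Alternatives covered the pseudocount (0.1), the filter on low values, median ratio scaling, quantile normalisation, a block by replicate number, limma without trend or with robust variance, the acinar list mean as a covariate, the threshold (0.1) and leaving out each islet library in turn, and for embryos and sperm the expression minimum, the pseudocount and the scaling. Restricting the gel fraction to sequences seen in whole sperm and scaling islets to FPKM outside Ins1, Ins2 and the acinar genes were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.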

Results

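The series traced small RNA from the sperm of male mice into embryos and offspring, and its title names sperm tsRNAs, which are fragments of transfer RNA. Mature sperm came from C57BL/6J males kept on a high-fat diet (HFD) or a normal diet (ND). RNA of 30 to 40 nt from either sperm was injected into fertilised eggs of the outbred ICR stock, and groups are named HFD or ND by the diet of the sperm donors. Of the 16 samples, 14 libraries were analysed, namely 4 small RNA libraries of sperm, 4 RNA-seq libraries of embryos and 6 RNA-seq libraries of pancreatic islets from the offspring. The 2 bisulfite libraries of islets were not analysed here. Whole sperm RNA gave 9517720 reads for ND and 9539556 for HFD. The RNA cut from a gel at 30 to 40 nt gave 10368455 reads for ND and 10605324 for HFD. Each embryo library was a pool of 5 embryos, with 1 library per group at the 8-cell stage (56 h after injection) and 1 per group at the blastocyst stage (75 h). The islets came from 3 libraries per group, taken after 6 h of fasting. Read depth of the embryo and islet libraries is unknown, since their values are FPKM (fragments scaled to transcript length and library size).

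The first comparison asked how the small RNA of sperm differed with the diet of the males. Whole sperm RNA held 2 main size groups, the 21-23 nt length of microRNAs and a broad group at 28-34 nt. Reads of 28-34 nt made up 51.5% of the ND library (95% Clopper-Pearson interval 51.5 to 51.5) and 55.1% of the HFD library (55.0 to 55.1). Reads of 21-23 nt made up 23% in ND and 23.9% in HFD (23.9 to 24.0). Longer reads of 35-45 nt made up 12.0% in ND (11.9 to 12.0) and 6.04% in HFD (6.02 to 6.05), a difference of -5.92 points that was -2.36 over unique sequences. Among these longer reads, 24.0% in ND and 15.2% in HFD ended in CCA, the bases at the 3′ end of mature transfer RNA, where equal use of the bases would give 1.56%. In the 30-40 nt libraries the shares of this length class were 1.32% and 0.713%. Intervals for sperm cover counting error only, since PCR reads are not independent molecules. With 1 library per group and size, no difference between sperm libraries was tested.

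**Figure D1:**
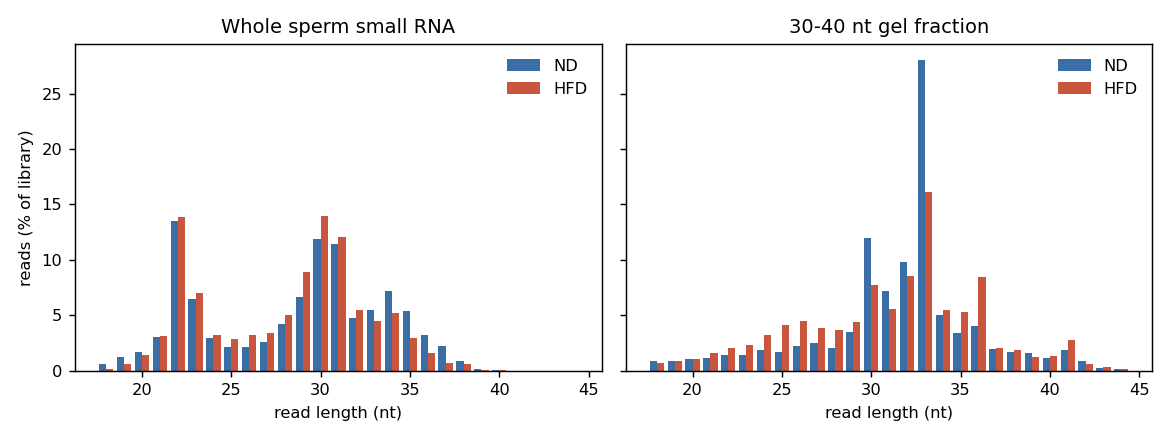
Read length in nt against percent of reads for whole sperm RNA (left) and the 30-40 nt gel fraction (right), with ND in blue and HFD in red; each bar is 1 library. Reads of 35-45 nt made up 12.0% of the whole ND library and 6.04% of the whole HFD library, and 17.2% and 24.2% of the 30-40 nt libraries.

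Reads of whole sperm RNA were grouped into families by their first 15 bases, and given by sequence because no reference of transfer RNA, ribosomal RNA or microRNA was used here. The family TGAGGTAGTAGGTTG, which begins as the let-7 microRNAs do, was the most abundant at 111336 RPM (reads scaled to library size) in ND and 94957 RPM in HFD. The family TCCCTGTGGTCTAGT stood at 32746 and 32804 RPM. Other families stood far apart between the diets. Family ACAGGAGATCCTGGG had 39579 RPM in ND and 5711 RPM in HFD, a ratio of HFD over ND of 0.144 (counting interval 0.143 to 0.146). CTCAGGGTCGTGGGT had 9127 RPM in ND and 277 RPM in HFD, a ratio of 0.0304 (0.0292 to 0.0316), and GCGAGAGGTCCCGGG had 6118 and 282 RPM, a ratio of 0.0461 (0.0443 to 0.0479). Their reads averaged 34.5, 36.8 and 34.6 nt, and these 3 families had no read in either 30-40 nt library, which allows up to 0.289 RPM in ND and 0.283 RPM in HFD. In the other direction, GCATTGGTGGTTCAG had 7331 RPM in ND and 18390 RPM in HFD, a ratio of 2.51 (2.49 to 2.53), and GCATTTGTGGTTCAG had 1113 and 2974 RPM, a ratio of 2.67 (2.61 to 2.73).

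**Figure D2:**
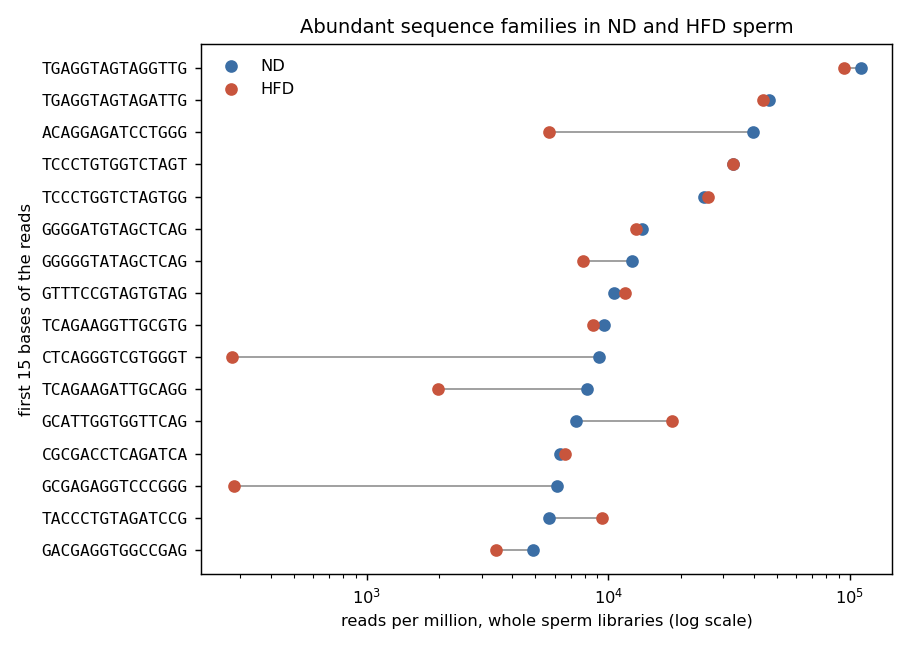
RPM on a log scale for abundant families of reads in whole sperm, named by their first 15 bases, with ND in blue and HFD in red; each point is 1 library and grey lines join the same family. ACAGGAGATCCTGGG stood at 39579 RPM in ND and 5711 RPM in HFD, while TCCCTGTGGTCTAGT stood at 32746 and 32804 RPM.

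By single sequences, the 22-nt sequence TGAGGTAGTAGGTTGTATGGTT had 36368 RPM in ND and 33388 RPM in HFD. Ratios were ranked among sequences with at least 100 RPM in either library and at least 10 RPM in both. The largest upward was 4.10 for ACCCTGTAGATCCGAATTTGTGA (79.4 RPM in ND, 326 RPM in HFD), and the largest downward was 0.0236 for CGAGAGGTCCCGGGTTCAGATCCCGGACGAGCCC (444 RPM and 10.5 RPM). Of 956 sequences with at least 100 RPM in either library, 349 differed by at least 2 times, 84 higher and 265 lower in HFD. The median sequence stood at a log2 ratio of -0.21, and after median ratio scaling 118 were higher and 241 lower.

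MicroRNA families were counted among reads of 21-23 nt by their seed, bases 2 to 8, so any RNA with those bases is included. The let-7 seed, the main one in the epididymal list, had 149132 RPM in ND and 134229 RPM in HFD, a ratio of 0.900 (0.898 to 0.902). The other 10 epididymal seeds were higher in HFD, among them miR-10a/10b at 6163 and 10523 RPM (ratio 1.71, 1.69 to 1.72) and miR-143 at 408 and 986 RPM (2.42, 2.33 to 2.51). All 7 germline seeds were higher in HFD, led in amount by miR-34b/34c, typical of male germ cells, at 2343 and 3662 RPM (1.56, 1.54 to 1.59). Of 9 seeds typical of somatic tissues, among them liver, blood, muscle and endothelium, 8 were higher in HFD, with miR-1, a muscle microRNA, at 940 and 1472 RPM (1.57, 1.52 to 1.61), miR-122, a liver microRNA, at 189 and 551 RPM (2.92, 2.77 to 3.08) and miR-451, abundant in red blood cells, at 75.2 and 211 RPM (2.80, 2.57 to 3.05). For miR-18a, miR-144, miR-223, miR-142, miR-126 and miR-133a the counting interval of the ratio included 1.

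RNA of 30 to 40 nt was injected into the zygotes, although no label states that the sequenced 30-40 nt RNA was the injected preparation. A larger share of its sequences differed between the diets than in whole sperm RNA. Family GTTTCCGTAGTGTAG had 263458 RPM in ND and 134442 RPM in HFD, a ratio of 0.510 (0.509 to 0.511), although in whole sperm it had 10539 and 11793 RPM. Its main sequence, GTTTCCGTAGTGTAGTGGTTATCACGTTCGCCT, alone made up 22.9% of ND reads and 11.6% of HFD reads. Family GCATTGGTGGTTCAG had 110851 RPM in ND and 79526 RPM in HFD (ratio 0.717, 0.715 to 0.719), opposite to its direction in whole sperm. That direction depends on the scaling to all reads. Over the 377 gel-fraction sequences of at least 100 RPM that whole sperm also held, the median log2 ratio was -0.75, which is lower than this family's. Family CGCGACCTCAGATCA had 49934 RPM in ND and 117846 RPM in HFD (2.36, 2.35 to 2.37), and its sequence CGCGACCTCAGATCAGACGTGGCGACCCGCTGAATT had 11871 and 59644 RPM. Sequences beginning GACTCTTAGCGGTGG were higher in HFD, the family having 476 RPM in ND and 2107 RPM in HFD (4.42, 4.29 to 4.56).

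By length, 76.0% of the ND reads and 63.8% of the HFD reads of the gel fraction lay between 30 and 40 nt. Reads of 28-34 nt made up 67.7% in ND (67.7 to 67.7) and 51.5% in HFD (51.5 to 51.6), and reads of 35-45 nt made up 17.2% (17.2 to 17.2) and 24.2% (24.1 to 24.2). These differences of -16.1 and 6.99 points were -4.48 and 2.41 over unique sequences, and -15.0 and 11.1 for sequences seen in whole sperm. Of 930 sequences with at least 100 RPM in either library, 687 differed by at least 2 times, 440 higher and 247 lower in HFD. The median log2 ratio was 0.30, and median ratio scaling gave 445 higher and 180 lower. Of these libraries, 31.8% of ND reads and 47.4% of HFD reads were in sequences without a read in either whole sperm library. Reads with any of 5 conserved sites of bacterial 16S ribosomal RNA stood at 909 RPM in the ND and 1810 RPM in the HFD gel fraction, against 5.88 and 14.4 RPM in whole sperm. Limited to the 377 sequences that whole sperm also held, a choice made after the data were seen, 215 differed by at least 2 times, 71 higher and 144 lower in HFD. Across 240 sequences of 30 to 40 nt with at least 10 RPM in all 4 libraries, the log2 ratios in whole and 30-40 nt RNA were weakly related (Pearson r = 0.15, Spearman correlation = 0.23), and 43.8% had the same sign. Across the 45 with at least 100 RPM in all 4 libraries Spearman correlation was 0.61. Sequences are not independent replicates.

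The next comparison asked which transcripts differed in embryos after injection of HFD rather than ND sperm RNA. The 10 largest differences upward at the 8-cell stage included single genes of the ribosome and of respiration. The ribosomal protein gene Rps7 (75.8 FPKM in ND, 335 in HFD) was higher in the HFD pool, as were Uqcr11 (28.7 and 142), a subunit of respiratory complex III, and Atp5j2 (5.75 and 26.1), a subunit of ATP synthase. Rps15 had 163 and 759 FPKM, but its listed locus is shared with or overlaps 29 other genes. The metallothionein Mt2, which binds metals, had the largest difference upward, 47.8 and 477 FPKM, and Actb, the cytoplasmic actin, had 38.8 and 220 FPKM. Esp24 (4.32 and 30.0), Rab33b (4.98 and 23.4) and the translation initiation factor gene Eif3k (9.60 and 41.9) were also among the 10 largest.

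On the lower side at the 8-cell stage, the small nucleolar RNA Snora78 had 642 FPKM in ND and 13.8 in HFD, a log2 difference of -5.44. Id3, an inhibitor of DNA-binding transcription factors, had 516 and 143 FPKM, and Tdgf1, a co-receptor of Nodal signalling, had 39.9 and 11.8. Amd2 (87.8 and 23.3) shares its locus with Amd1, Plet1 (44.3 and 12.9) overlaps Plet1os, and Man2c1os (24.3 and 6.08) overlaps Man2c1, so each value is less certain. Ube2dnl1 (45.2 and 12.4), Hibch (20.9 and 5.65), an enzyme of valine breakdown, Lsm10 (46.2 and 14.4) and Fam120aos (17.9 and 5.25) completed the 10 largest. Of 3687 genes with a mean of at least 10 FPKM, 255 differed by at least 1 on the log2 scale, 72 higher and 183 lower in HFD. The median gene stood at -0.32 (SD over genes 0.51), and after median ratio scaling 134 were higher and 38 lower, so the balance of directions depended on the scaling.

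In blastocysts other genes led. Lgals1, which encodes the lectin galectin-1, had 868 FPKM in ND and 3869 in HFD, and the actin-binding Tmsb4x had 269 and 1062. H2-K1, a class I histocompatibility gene (13.6 and 53), the interferon-induced family member Oas1f (3.13 and 17.2), Ndrg1 (8.79 and 38.9), Tmprss2 (6.62 and 25.7), the alkaline phosphatase gene Alpl (4.44 and 17.1) and the complex I subunit gene Ndufs5 (43.9 and 142) were also higher. Lower in the HFD pool were Eif5a, a translation factor (825 and 185), the tight junction gene Cldn6 (104 and 25.8), the transcription factor gene Osr2 (16.9 and 3.19), Plaur, the urokinase receptor (43.3 and 12.2), Thrsp, linked to fat synthesis (25.0 and 6.07), Dhrs7 (21.7 and 4.96), Cpn1 (89.4 and 23.2) and Rnd3 (19 and 5.12). Fam98c (22.2 and 5.39) overlaps Rasgrp4. The adenosylmethionine decarboxylase genes Amd1 (0.0271 and 58.6) and Amd2 (99.9 and 9.19) share a locus and differed in opposite directions, and their sum was 99.9 in ND and 67.7 in HFD.

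Of 4134 genes measured in blastocysts, 256 differed by at least 1 on the log2 scale, 53 higher and 203 lower in HFD. The median gene stood at -0.18 (SD over genes 0.53), and median ratio scaling gave 102 higher and 101 lower. Eif3j2 was listed at 0 in the ND blastocysts and at 13.3 FPKM in the HFD blastocysts, with 51.3 and 56.6 FPKM at the 8-cell stage. Each stage had 1 pool per group, so these are differences in size without a test.

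Gene lists were set against 10000 random lists of the same size and expression. At the 8-cell stage, all 9 measured genes of fatty acid oxidation were lower in HFD, and 8 of 9 lay below the median gene, which stood at -0.32. Their median log2 difference was -0.82 at percentile 0.085, and they included Acadm (283 and 149 FPKM) and Hadhb (85.8 and 48.1). The TCA cycle had 15 of 17 genes lower and 13 of 17 below the median gene (median -0.59, percentile 1.90). Among them were Mdh2 (561 and 346) and Pdhb (336 and 218). The 3 measured genes of 2-cell and zygotic activation, Eif1a, Tdpoz2 and Tdpoz4, were lower as well (median -1.13, percentile 0.295). Cytosolic ribosomal protein genes were higher in 29 of 49 (median 0.18, at percentile 100), and 39 of 49 lay above the median gene. Oxidative phosphorylation genes had 33 of 51 above the median gene (percentile 99.6), although 32 of 51 were lower in HFD before scaling and the list median was -0.17. The imprinted list had a median of 0.19 over 7 genes (percentile 99.4) but a mean of -0.12, with Phlda2 at 167 and 276 FPKM and Snrpn at 103 and 46.3.

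In blastocysts, cholesterol synthesis genes stood out on the lower side, with 16 of 17 lower in HFD and 14 of 17 below the median gene, which stood at -0.18. Their median was -0.69 (percentile 0.040). Fdft1, squalene synthase, had 82.6 FPKM in ND and 29.3 in HFD, Cyp51 had 23.9 and 8.25, and Idi1 had 76.7 and 33.8. Genes of the unfolded protein response were lower in 16 of 17 and below the median gene in 14 of 17 (median -0.57, percentile 0.620). Among them were the protein disulfide isomerase gene Pdia3 (172 and 53.7) and the chaperone gene Hspa5 (253 and 188). Oxidative phosphorylation genes were higher in 38 of 52 (median 0.33, at percentile 100), including Uqcrq (2607 and 3959) and Ndufa4 (1024 and 1639), and cytosolic ribosomal protein genes had a median of 0.09 (percentile 93.5). Fatty acid oxidation genes, lower at the 8-cell stage, were lower in 8 of 16 in blastocysts (percentile 90.2). Of 22 lists at each stage, 3 lay below and 3 above the central 95% of random lists at the 8-cell stage, and 2 below and 1 above in blastocysts. Among genes outside both lists, those in the lowest 10% of genomic span stood 0.19 above the median gene at the 8-cell stage and 0.09 above it in blastocysts.

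The same direction at both stages was seen in a small set of genes. Ndufs5, Tmsb4x and 5430416N02Rik were higher by at least 1 on the log2 scale at both stages, where independence would give 0.313 genes. Lower at both were 16 genes, where independence would give 7.19, including the cholesterol precursor enzymes Acat2 and Idi1, Cldn6, Plaur, the endosomal GTPase gene Rab7, the imprinted gene Snrpn and the stress gene Sdf2l1. Both counts were made before scaling, when the median gene stood at -0.32 at the 8-cell stage and -0.18 in blastocysts. Of the 16, Amd2 lay lowest at the 8-cell stage (log2 difference -1.87, or -1.54 after median ratio scaling). The others lay between -1.32 and -1.03 there, near the threshold. The overlap was not counted after scaling. Across 3157 genes measured at both stages, the log2 differences were weakly related (Pearson r = 0.26, Spearman correlation = 0.29); genes are not independent replicates. In a limma model of stage and injection over the 4 embryo libraries, with 1 residual degree of freedom, 0 of 9603 genes passed an adjusted p of 0.05 for the injection, and 1165 had an unadjusted p under 0.05 (211 higher, 954 lower in HFD; 431 and 477 after median ratio scaling). The stage effect passed for 4609 genes, 3059 higher and 1550 lower in blastocysts (2380 and 2263 after scaling). Trophectoderm genes rose towards the blastocyst in 17 of 22 and fell in 2, and maternal oocyte genes fell in 10 of 15 and rose in 4.

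The last comparison asked how islets of the offspring differed with the RNA injected into the zygote. Islets are clusters of hormone cells in the pancreas, surrounded in the tissue by acinar cells, which make digestive enzymes. In the HFD islets 5 genes rose. Dio1, the deiodinase that activates thyroid hormone, rose from 1.93 ± 0.344 to 28.2 ± 15.0 FPKM (mean ± SD, n = 3 per group; log2 difference 3.20, SE 0.28, limma adjusted p = 0.000320). Kcnj5, a subunit of a potassium channel opened by G proteins, rose from 0.196 ± 0.0547 to 5.94 ± 2.34 FPKM (log2 difference 2.49, SE 0.21, limma adjusted p = 0.000320). Rgcc, a regulator of the cell cycle, rose from 6.64 ± 0.843 to 21.4 ± 4.84 FPKM (1.53, SE 0.19, limma adjusted p = 0.00894), and Echdc2, an enzyme of the enoyl-CoA hydratase family, rose from 12.9 ± 1.51 to 29.3 ± 2.93 FPKM (1.13, SE 0.17, limma adjusted p = 0.0355). The pseudogene Marcksl1-ps4 rose from 0.873 ± 0.706 to 5.11 ± 1.45 FPKM (1.75, SE 0.26, limma adjusted p = 0.0355). Tmed11, of the p24 family of secretory cargo proteins, fell from 34.5 ± 9.79 to 11 ± 3.26 FPKM (-1.62, SE 0.25, limma adjusted p = 0.0418). For each of the 6 genes the HFD and ND libraries did not overlap, which chance gives for 10% of genes where the groups do not differ. These genes were picked by their p in the same libraries, so the separation adds no support. The median of all genes was itself 0.30 higher in HFD on the log2 scale. Kcnj5 and Marcksl1-ps4 fell outside the rule for named genes because of their low mean, and were named after their values were seen.

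In mm10 coordinates, Dio1 lies on chromosome 4 from 107291465 to 107307143 and Echdc2 on the same chromosome from 108165437 to 108179308. Kcnj5 lies on chromosome 9 from 32314783 to 32344237, Rgcc on chromosome 14 from 79288750 to 79301635, Marcksl1-ps4 on chromosome 13 from 4248735 to 4249777 and Tmed11 on chromosome 5 from 108777235 to 108795363. Dio1 and Echdc2 lie near each other, and their rises were not shown to be independent. The zygotes came from the outbred ICR stock, and differences in genotype between the islet libraries were not tested.

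These 6 genes were the calls among 11737 tested by limma, and 3576 genes had an unadjusted p under 0.05, 3477 of them higher in HFD. The median of all genes stood at a log2 difference of 0.30, and relative to it Dio1 lay at 2.90, Kcnj5 at 2.19, Rgcc at 1.23, Echdc2 at 0.83, Marcksl1-ps4 at 1.45 and Tmed11 at -1.92. After median ratio scaling, 605 were higher and 557 lower at an unadjusted p under 0.05, and the calls were Kcnj5 and Dio1 alone (limma adjusted p = 0.0396 and 0.0451). ND replicate 1 stood apart, with a score of -46.9 on a principal component that held 61.4% of the variance, and with 10861 genes at 1 FPKM or more against 11481 to 11975 in the other libraries. The number of calls rested on single libraries: it was 0 without ND replicate 1 (2209 at an unadjusted p under 0.05), 2 without ND replicate 2, 347 without ND replicate 3, 22 without HFD replicate 2 and 36 without HFD replicate 3. It was also 0 without a filter on low values, 0 after quantile normalisation and 0 with the acinar list mean as a covariate, with 3904, 1168 and 295 genes at an unadjusted p under 0.05. No label states that the islet libraries come from separate animals, so p-values measure the spread between these samples only.

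**Figure D3:**
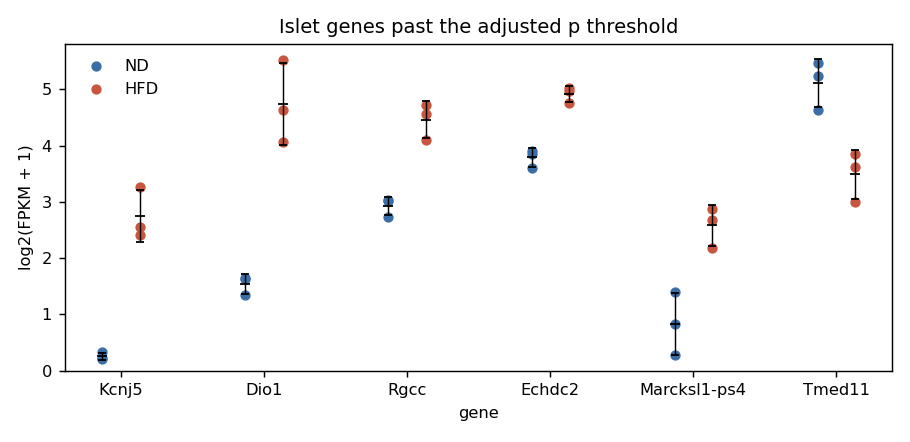
Expression as log2(FPKM + 1) of the 6 genes past an adjusted p of 0.05 in islets, with the 3 ND libraries in blue and the 3 HFD libraries in red; black marks are the mean and SD of each group. Dio1 went from a mean of 1.93 to 28.2 FPKM and Tmed11 from 34.5 to 11 FPKM, and the groups did not overlap.

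Below the threshold, the genes with the lowest p on the higher side had log2 differences between 0.83 and 1.51. Gcgr, the glucagon receptor, had 11.8 ± 1.56 FPKM in ND and 26.5 ± 4.41 in HFD (n = 3 per group; limma adjusted p = 0.0501), and Nr1d1, a repressor of the circadian clock, had 9.47 ± 4.30 and 27.8 ± 7.66 (limma adjusted p = 0.0748). Dusp5, a phosphatase of ERK kinases, had 4.50 ± 0.485 and 10.2 ± 1.78. Stmn3, Slc44a2, Ppap2a, Mcam, Tmem204 and Ppap2b had log2 differences between 0.83 and 0.93. On the lower side, several genes belong to acinar cells: Gp2, a protein of their secretory granules, had 1128 ± 153 FPKM in ND and 528 ± 170 in HFD, Reg1 had 5170 ± 484 and 2510 ± 359, Dmbt1 had 763 ± 58.4 and 402 ± 150, and Ptf1a, their transcription factor, had 9.44 ± 3.02 and 4.65 ± 0.119. Hamp2 (44.2 ± 2.00 and 17.6 ± 7.10), a hepcidin, and Gnmt (24.5 ± 1.99 and 13.5 ± 2.17), a glycine methyltransferase, were lower too. Cckar, the receptor for cholecystokinin, Serpinb1a, Gls2, Fam134b and Sostdc1 had log2 differences between -1.14 and -0.88.

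Relative to all genes, the acinar list had the largest median shift of the 33 lists in islets. Of its 34 tested genes, 32 were lower in HFD and 33 lay below the median gene, with a median log2 difference of -0.79, or -1.09 relative to all genes. Digestive enzyme genes had values such as 57650 ± 11115 and 35227 ± 14801 FPKM for Ctrb1 and 27386 ± 4185 and 15729 ± 5966 for Prss2. Over all genes 0 passed in limma, with 19 at an unadjusted p under 0.05, and 15 fell when adjusted over the list alone. Camera, which compares a list with the other genes, gave an adjusted p of 4.17e-80 at the preset correlation of 0.01. The camera adjusted p was 0.261 with an estimated correlation, which was 0.59 for this list. As a share of all FPKM, the acinar list took 34.8% ± 6.09 in ND and 17.9% ± 7.75 in HFD (SD, n = 3; exact permutation p = 0.1, two-sided). Ins1 and Ins2, the insulin genes, took 42.2% ± 5.29 in ND and 57.0% ± 7.90 in HFD (exact permutation p = 0.1). With 3 libraries against 3, an exact permutation test cannot go below 0.1, and the mean of the acinar list gave an exact permutation p of 0.2. Tmed11, the gene called as lower, nearly followed the acinar share across the libraries. In ND both were highest in replicate 1 (42.96 FPKM and 39.63%) and lowest in replicate 2 (23.77 FPKM and 27.98%). In HFD both were lowest in replicate 1, while replicates 2 and 3 stood in opposite order. The fall of Tmed11 was thus not told apart from a lower acinar share.

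Endothelial and stromal genes stood on the higher side in HFD, beside the lower acinar share. All 14 endothelial genes were higher (median 0.75, or 0.45 relative to all genes; camera adjusted p = 6.26e-06, and 0.997 with an estimated correlation), for example Plvap at 57.7 ± 12.3 and 113 ± 21.3 FPKM and Kdr at 16.1 ± 3.65 and 26.9 ± 2.28. All 18 stromal and stellate genes were higher (median 0.71, or 0.41 relative to all genes; camera adjusted p = 2.93e-05, and 0.997 with an estimated correlation), for example Sparc at 25.0 ± 5.41 and 46.9 ± 5.95. Adjusted over the list alone, 13 endothelial and 14 stromal genes passed in limma as higher. Adjusted over all genes, 0 of either list passed, before or after median ratio scaling. Of all 11737 genes, 3477 were higher at an unadjusted p under 0.05, so the shift of all genes enters counts made over a list alone. Immediate early genes, quickly induced on stimulation, were higher in 18 of 19 (median 0.62, or 0.32 relative to all), with Fos at 130 ± 25.2 and 202 ± 50.9. Camera gave an adjusted p of 0.00647, and 0.997 with an estimated correlation. Adjusted over the list alone 12 passed in limma as higher, and over all genes 0. The camera adjusted p of the immediate early list was 0.362 without ND replicate 2 and 0.101 without HFD replicate 1, where the shift was 0.15.

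The list of alpha, delta and PP cells had 8 of 13 genes lower in HFD and 10 of 13 below the median gene (median -0.20, or -0.50 relative to all; camera adjusted p = 1.99e-06, and 0.389 with an estimated correlation). The shift relative to all genes was -0.17 without ND replicate 2 and -0.30 without HFD replicate 3. Glucagon, Gcg, had 2838 ± 815 and 2027 ± 896 FPKM, and somatostatin, Sst, had 1697 ± 780 and 1171 ± 643, while Ttr and Gc had log2 differences of 0.72 and 0.83. Adjusted over the list alone, 0 genes passed in limma and 2 had an unadjusted p under 0.05. Its mean per library gave an exact permutation p of 0.9. Beta cell identity genes were higher in 25 of 25 (median 0.50, or 0.20 relative to all; camera adjusted p = 0.260). Relative to all genes they lay at 0.11 without ND replicate 1, 0.32 without ND replicate 2 (camera adjusted p = 0.0174), 0.08 without ND replicate 3 and 0.12 without HFD replicate 3, and camera gave 0.0232 without HFD replicate 1. Among them were Ins1 at 36048 ± 7626 and 66798 ± 14633 FPKM and Pdx1 at a log2 difference of 0.50; adjusted over the list alone 0 passed in limma, and 8 had an unadjusted p under 0.05. Insulin secretion genes were higher in 30 of 30 (median 0.41, or 0.11 relative to all; camera adjusted p = 0.0578). Without ND replicate 2 or HFD replicates 1 or 2 camera gave 0.00319, 0.00674 and 0.0296, the first 2 with shifts of 0.19 and 0.17. Adjusted over the list alone 5 passed in limma as higher, among them Chgb (258 ± 42.6 and 522 ± 175 FPKM), and over all genes 0.

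Of 33 lists, camera called 6 at an adjusted p under 0.05, and 0 with an estimated correlation. Camera placed growth and regeneration genes lower (adjusted p = 0.0138), although their median and mean were 0.19 and 0.06 above those of all genes. That call was lost under median ratio scaling (adjusted p = 0.730), with an estimated correlation (0.389) and without HFD replicates 2 (0.0814) or 3 (0.339), and its direction turned without ND replicate 3 (0.695). The number of called lists was 10 without ND replicate 2 and 12 without HFD replicate 3. By fry, which asks whether a list's genes move on balance in 1 direction, 0 lists passed, with a lowest adjusted p of 0.118. Its mixed form, which counts changes in either direction, passed the duct list alone (adjusted p by limma = 0.0426). Oxidative phosphorylation genes were higher in 52 of 52, but by a median of 0.37, which is 0.07 relative to all genes (camera adjusted p = 0.0614). This was 0.16 without ND replicate 1 (0.000449), -0.03 without ND replicate 3, 0.02 without HFD replicate 1, 0.05 without HFD replicate 2 and 0.14 without HFD replicate 3 (0.00705), and camera gave 0.0345 without ND replicate 2.

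**Figure D4:**
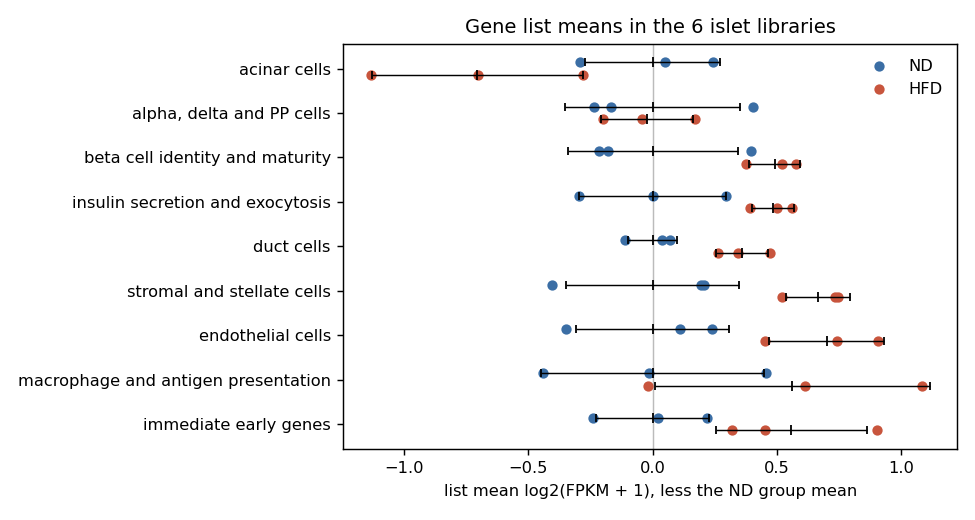
Mean log2(FPKM + 1) of 9 gene lists in each islet library, less the mean of the ND group, with ND in blue and HFD in red; black marks are the mean and SD over 3 libraries. The acinar list lies lower in HFD by a mean of 0.71, while the endothelial list lies higher by 0.70; the exact permutation p was 0.2 and 0.1.

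Changes in embryos and in islets were compared gene by gene. Across 7229 genes of at least 1 FPKM, islet and 8-cell differences had a Spearman correlation of 0.13, and across 7891 genes islet and blastocyst differences had a Spearman correlation of 0.08. Over all genes 54.6% and 52.1% lay on the same side of the median gene in both.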

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

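The tests of acinar cells, of the alpha, delta and PP list, of read depth in sperm, of genes matched on span and of splits of the islet libraries were chosen only after the result was seen; those of bacterial sites and of the lowest 10% of span were set before.

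In the 30-40 nt sperm libraries, 31.8% of ND reads and 47.4% of HFD reads were in sequences without a read in whole sperm RNA, which is a signal outside the whole sperm data. Too few reads in whole sperm do not account for most of this: 48.7% of these sequences, but 5.95% of their reads, were in sequences expected under 3 reads there from their share among reads of the same length. Reads with a conserved bacterial 16S site stood at 909 RPM in ND and 1810 RPM in HFD in the gel fraction, at least 63.3 times the level in whole sperm RNA, so RNA of bacteria may have entered with the gel step. How much of the absent sequence it makes up was not measured. A difference between the diets in what the gel fraction holds stays open and was not tested, since each group had 1 library.

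The acinar list lay lower in HFD islets, with 97.1% of its tested genes below the median gene, a pattern that fewer acinar cells carried over with the islets could produce. The same explanation would raise the markers of every other cell type alike. The lower quartile of the endothelial genes lay 0.38 above the upper quartile of the alpha, delta and PP genes on the log2 scale. This gap was 0.20 without ND replicate 2, 0.23 without HFD replicate 1, and 0.27 to 0.56 without any other library. That upper quartile (0.212) lay above the lower quartiles of the duct genes (0.207) and of the Schwann and neuron genes (0.208). The result thus depended on the list compared. It cannot decide whether a lower acinar share alone accounts for the lower position of the alpha, delta and PP list. The acinar list held 34.8% of FPKM in ND and 17.9% in HFD (exact permutation p = 0.1). A change in acinar transcripts or islet hormone cells of the offspring with the injected RNA stays open and was not tested apart from cell numbers.

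Ribosomal protein and oxidative phosphorylation genes lay above the median gene in HFD embryos, and a bias towards genes of small genomic span was tested as a source. At the 8-cell stage, other genes in the lowest 10% of span lay 0.19 above the median gene (interval 0.13 to 0.27), against a shift of 0.15 for oxidative phosphorylation, and in blastocysts they lay 0.0943 above it (0.01 to 0.18), against a shift of 0.28 for ribosomal proteins. Other genes matched on span to oxidative phosphorylation genes in blastocysts lay at -0.00990 (-0.17 to 0.16), below the list's shift of 0.51 (0.33 to 0.58), which argues against span bias as the whole source there. Matched genes lay at 0.0354 for oxidative phosphorylation at the 8-cell stage (-0.11 to 0.19; list 0.15), and at 0.115 (-0.04 to 0.30; list 0.50) and 0.0463 (-0.13 to 0.22; list 0.28) for ribosomal proteins at the 8-cell and blastocyst stages. For these 3 shifts span bias and an effect of the injected RNA cannot be told apart, because the limits of the matched genes and of the lists overlap. Variation between pools cannot be told apart from either, also for oxidative phosphorylation in blastocysts. Each stage had 1 pool per group, and the limits are over genes. The sets above were matched on span and not on expression. In blastocysts, random lists of like expression had medians of -0.017 for oxidative phosphorylation and -0.005 for ribosomal proteins, against -0.181 for the median gene. At the 8-cell stage these medians were -0.372 and -0.334, against -0.322. In blastocysts a part of both shifts thus goes with expression.

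Among genes with a mean of at least 10 FPKM at both stages, 1 gene differed in direction by at least 1 on the log2 scale at both: Gpx2, a glutathione peroxidase, had 4.85 FPKM in ND and 20.9 in HFD at the 8-cell stage, and 53.3 and 19 in blastocysts. The difference between the stages was not tested.

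For the islet gene count, 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real split gave 6 genes, and 1 of the 10 splits (the real one) gave as many, with 4 as the highest of the others. For the islet lists the real split gave 6 calls and all 10 splits gave as many or more, with 14 as the highest of the others.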

How the results depend on the processing

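All alternatives were planned except scaling outside Ins1, Ins2 and acinar genes and the limit to sequences seen in whole sperm, which were chosen after the data were seen. Against 6 genes, the count was 3 with a pseudocount of 0.1, 0 without a filter, 9 with at least 5 FPKM in 3 libraries (4 of them among the 6), 2 with median ratio scaling, 0 with quantile normalisation, 10 without trend, 21 with robust variance, 0 with the acinar list mean as covariate, 38 at an adjusted p under 0.1 (a wider threshold by construction) and 3 with scaling outside Ins1, Ins2 and acinar genes. Leaving out each library gave 0 to 347. With a block by replicate number the count was 590 and the number of lists 10. Residual correlations of libraries with the same number were -0.03, 0.04 and 0.03, and those of other pairs ran from -0.06 to 0.03. These values give no sign that the numbers pair the libraries, but cannot exclude it. Against 6 lists, median ratio scaling gave 11, an estimated correlation 0, and leaving out each library 7 to 12. The acinar list mean stayed lower in HFD in every such fit, by -0.92 to -0.49. For the growth and regeneration list, called as lower by camera although its median lay 0.19 above that of all genes, camera turned to higher with the block (median 0.19, adjusted p = 0.807 by limma) and without ND replicate 3 (0.26, adjusted p = 0.695); the median itself turned sign without ND replicate 1 (-0.14) and without HFD replicate 1 (-0.02). The cause was not tested for any of these.

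At a mean of at least 1 FPKM, 686 genes differed at the 8-cell stage and 573 in blastocysts, and at a mean of at least 50 FPKM 79 and 87, as the minimum changes how many genes are counted. The 0 injection calls and the calls by stage stayed within 1.5 times under all alternatives run. Across genes, the Spearman correlation between the stages was 0.35 at 50 FPKM or more; correlations were compared by a Fisher interval over genes. In whole sperm, HFD minus ND in percent of reads without the most abundant sequence was 0.679 for 21-23 nt, 4.34 for 28-34 nt and -6.32 for 35-45 nt. With at least 10 reads per sequence it was 1.89, 3.42 and -6.47, and over unique sequences 0.0489, 3.08 and -2.36. In the 30-40 nt libraries it was -12.9 for 28-34 nt and 5.07 for 35-45 nt without the most abundant sequence, -16.1 and 6.90 with at least 10 reads, -4.48 and 2.41 over unique sequences, and -15.0 and 11.1 for sequences seen in whole sperm. Sequences that differed numbered 2211 at 10 RPM and 35 at 1000 RPM in whole sperm, 6925 and 59 in the gel fraction, and 215 there for sequences seen in whole sperm. The Spearman correlation between both kinds of RNA was 0.61 at 100 RPM in all 4 libraries. The cause was not tested for these shifts.

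Of other values under alternatives, 808 stayed within the bounds set for them, 91 newly passed it, 39 no longer passed it and 1 moved. Classes of RNA and isoacceptors under alternatives, and a denominator of 15-45 nt, were not run, the latter because the tables hold no other lengths. Depth limits the rare sperm seeds, as for miR-144 with 4 and 5 reads (ratio interval 0.268 to 6.29) and miR-126 with 0 and 3 reads. The depth of the FPKM tables is unknown.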

Other observations

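No test was added for this part. Of the immune lists in islets none passed camera over all 6 libraries, with an adjusted p by limma of 0.240 for macrophage and antigen presentation, 0.143 for interferon and inflammation and 0.128 for lymphoid cells. Of 17 macrophage and antigen presentation genes 16 were higher (median log2 difference 0.65, or 0.35 relative to all genes; 0.23 without ND replicate 3, 0.13 without HFD replicate 2, and 0.61 without HFD replicate 3, where camera called the list), with Cd74 at 46.8 ± 23.5 FPKM in ND and 95.6 ± 35.6 in HFD (mean ± SD, n = 3) and Lyz2 at 28.5 ± 10.4 and 53.9 ± 23.7. Adjusted over the list alone 6 passed in limma as higher, and over all genes 0. The list mean gave an exact permutation p of 0.3. The 3 lymphoid genes measured, of 18 in the list, were higher (median 0.86, or 0.56 relative to all genes), among them Igj at 1.68 ± 0.367 and 7.50 ± 5.55. Their shift was 0.20 without HFD replicate 2. Camera called the lymphoid list without ND replicate 3 (adjusted p = 0.000279), HFD replicate 1 (0.00144) or HFD replicate 3 (0.000641), and not without any of the others. Of 15 interferon and inflammation genes all were higher (median 0.38, or 0.08 relative to all genes), with Socs3 at 9.19 ± 1.84 and 19.2 ± 5.84. The shift was 0.04 to 0.20 with 1 library left out, and camera called the list only without HFD replicate 3 (adjusted p = 0.00847). Adjusted over the list alone 6 passed in limma as higher, and over all genes 0. The blood cell genes Hbb-b1 (46.3 ± 45.4 and 74.1 ± 56.7) and Hba-a1 (44 ± 42.1 and 76.3 ± 62.3) varied within groups as much as between them. Duct genes were higher in 9 of 12, with Spp1 at 55.0 ± 13.0 and 120 ± 39.0 FPKM, while Tff2 had 804 ± 79.5 and 592 ± 231.

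In islets, glycolysis and gluconeogenesis genes were higher in 26 of 27 (median 0.44, or 0.14 relative to all genes; camera adjusted p = 0.0937 by limma, and 0.0340 without HFD replicate 3), and their shift was 0.08 without ND replicate 3 and 0.09 without HFD replicate 2, with Pkm at 115 ± 26.6 and 165 ± 16.4. The 10 glycolysis genes measured in blastocysts had a median of 0.17 at percentile 97.0, inside the central 95% of random lists, as were the 4 primitive endoderm genes measured, at a median of 0.34 and percentile 97.4.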
